A study of Solanum lycopersicum with 6 samples.

How the data were processed

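Total RNA from 6 leaf disc samples was labelled with cyanine-3 and hybridised to 1-colour Agilent tomato arrays, from 500 ng of RNA per the labels' protocols. Plants grew at 25 °C under days of 16 h and nights of 8 h, per the labels' protocols. The authors deposited the scanner output of each array, whose spot intensity was background-subtracted and detrended by Agilent Feature Extraction, per the file headers. The headers give version 11.5.1.1 of this program and the submitters' processing notes give version 9.1. These deposited intensity values are not normalised between arrays. The deposited flags per spot mark signals well above background, saturated signals and outliers, per the file headers. The authors also deposited a table of log2 ratios of loliolide over methanol for 27 probes and 3 numbered pairs. Its values were compared with the differences of the log2 scanner signals after each array was scaled as described below. The deposited ratios equalled these differences up to 1 constant per pair, of -0.01, 0.01 and 0.05 on the log2 scale.

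The log2 of the processed signal was taken and each array's 75th percentile over non-control spots was subtracted. Spots flagged as outliers, between 0 and 5 per array, were left out, and no spot was saturated. Spots of 1 probe were averaged. A probe was tested where it was well above background on all arrays of at least 1 group, which kept 37423 probes and left out 6180. Loliolide was compared with methanol by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was represented by its probe with the highest mean signal over all 6 arrays, and p-values were adjusted again over these probes. An accession on the array without a named gene counted as 1 gene, and several such accessions may belong to the same gene. A level under background in a whole group gave a bound only.

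Accessions on the array were matched to RefSeq genes of assembly SLM_r2.1. This named 2576 probes of 1191 genes, or 5.91% of the probes, and 305 of these genes have only a LOC number. A further 121 probes with RefSeq accessions had no match, and 41027 probes are unnamed here. Most of the response is therefore described by probe counts. The reference gave symbols and no descriptions, so that 11 of 35 planned gene lists reached 5 tested genes and the 24 others were not tested. A further 23 lists were written from gene symbols before any model was fitted, but after the values of the 27 deposited probes, lin5 among them, had been seen. After a first fit 2 symbols were respelled and 1 was removed. These lists are reported only among the closing observations. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry.

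Genes were named by a rule fixed before the data were examined. It took the named genes past an adjusted p of 0.05 with groups that did not overlap, up to 15 higher and 10 lower. Where fewer passed, it added the named genes with the smallest unadjusted p up to 10 per direction. It also took up to 4 passing members of each list and the named genes of the deposited table. On simulated data for the comparison of loliolide with methanol, with 37413 probes, 53 of 100 probes changed 2-fold and 89 of 100 changed 4-fold were called, along with 7 unchanged probes. Of 20 simulated lists of 15 genes shifted by -0.4, 20 were called, as was 1 of 100 unshifted lists. The simulated noise was independent between probes and held no slide effect. These simulated counts therefore do not cover genes that vary together or a difference between slides. Alternatives covered background correction, scaling, filters, the variance model, array weights, the replicate numbers and each array left out in turn. The slide could not be fitted as a block because each of the 2 slides holds 1 group. The spread between arrays, rather than a read depth, sets the precision.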

Results

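Gene expression was measured in leaf discs of tomato (Solanum lycopersicum) cultivar Micro-Tom, a dwarf laboratory line. Discs of 1 cm were floated for 12 h on 300 µM loliolide, a metabolite of carotenoids, or on 0.1% methanol as the control. Each of the 6 samples was hybridised to its own 1-colour Agilent array, 3 for loliolide and 3 for methanol. The arrays carried 43603 distinct non-control probes. On the methanol arrays 84.5% to 85.3% of the spots were well above background, and on the loliolide arrays 86.93% to 87.62%. The scanner program's detection limit for spike-ins, on a log10 scale, was 1.871 to 1.895 on the methanol arrays and 2.147 to 2.247 on the loliolide arrays. The number of arrays limits the precision. The 75th percentile of the signal lay between 1048 and 1117 on 5 arrays and at 817.7 on the array of loliolide replicate 3. Across probes, Pearson's r between arrays ranged from 0.9793 to 0.996, where probes are not independent replicates. The labels speak of triplicate harvests and do not name separate plants, so the p-values measure the spread between these samples only. All 3 methanol arrays lay on one slide and all 3 loliolide arrays on another, and the slides were scanned separately. Slide and treatment cannot be told apart in any comparison of this series.

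The first comparison asked which tomato genes responded to loliolide, the purpose given by the title of the series. Among the named genes that passed and were well above background on all 6 arrays, the highest rise was that of lin5 (gene 544241), which encodes a cell-wall invertase that splits sucrose outside the cell. Its log2 signal was -2.07 ± 0.07 (SD, n = 3) with loliolide and -3.84 ± 0.32 (SD, n = 3) with methanol, a difference of 1.77 (SE 0.17, limma adjusted p = 0.0119). The gene lies on chromosome 9 from 3976833 to 3980696 of assembly SLM_r2.1. ACS2 (gene 606304, chromosome 1 from 82261079 to 82263995), which makes the precursor of ethylene, rose 1.73-fold (limma adjusted p = 0.0252), and its other probe was higher by 0.95 on the log2 scale without passing. MT2 (gene 778299, chromosome 6 from 499687 to 501207), a metallothionein-like gene, rose 1.64-fold (limma adjusted p = 0.032), and its other probe was higher by 0.84. The small heat shock protein gene vis1 (gene 543846, chromosome 5 from 8420977 to 8423572) rose 2.22-fold (limma adjusted p = 0.0465, 0.0576 over all probes). CS2 (gene 544151, chromosome 4 from 3574338 to 3582713) rose 1.85-fold (limma adjusted p = 0.0378). LOC101248771 (chromosome 4 from 66067862 to 66075948) was not well above background on any methanol array and was at least 1.89-fold higher with loliolide (limma adjusted p = 0.00886). This bound sets the mean of the loliolide arrays against the lowest signal well above background on each methanol array, or the probe's own signal where higher. The phosphate transporter gene PT2 (gene 543546, chromosome 3 from 1275009 to 1276649) was the 1 named gene that passed with lower signal, at -1.02 on the log2 scale (SE 0.17, limma adjusted p = 0.0495, 0.0612 over all probes). In each of these genes the 3 loliolide arrays lay all above or all below the 3 methanol arrays, as the naming rule required. The call of LOC101248771 held without each array in turn, that of lin5 in 3 of these 6 fits, and those of ACS2, MT2, vis1, CS2 and PT2 in 0 of 6. Of 5 other scalings or background corrections, lin5 passed with 5, LOC101248771 with 4, MT2 with 3, ACS2 and PT2 with 2, CS2 with 1 and vis1 with 0. With normexp background correction, chosen after seeing the data, the difference of LOC101248771 was 0.36 (limma adjusted p = 0.189), under its bound, and that of PT2 was -0.24 (limma adjusted p = 0.283). The offset of 50 added in this correction shrinks the log2 differences of dim probes by construction. These differences therefore do not show what background correction alone would give.

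**Figure D1:**
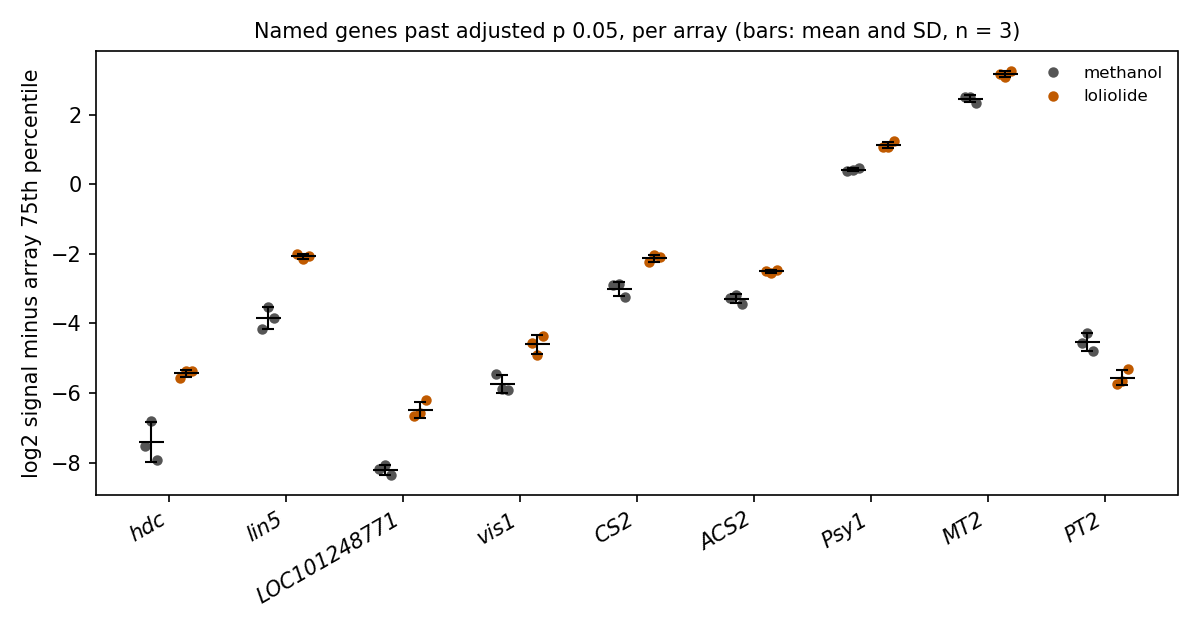
Log2 signal minus the array's 75th percentile (vertical axis) of the 9 named genes past an adjusted p of 0.05, with 1 point per array and bars for the mean and SD of 3 arrays. The loliolide arrays lie above the methanol arrays for 8 genes and below them for PT2, and signals of different genes are not comparable with each other.

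Probes of the same gene disagreed for 2 further genes. Psy1 (gene 543988, chromosome 3 from 5586036 to 5591181), the phytoene synthase that opens carotenoid synthesis, was represented by its brightest probe, which rose 1.64-fold (limma adjusted p = 0.0266). All of its 7 other tested probes were lower with loliolide, by log2 differences between -0.35 and -0.11, and none of these passed. With the mean over all its probes the difference was -0.12 (limma adjusted p = 0.561). The representative probe of hdc (gene 544085, chromosome 8 from 56154894 to 56158282), a histidine decarboxylase gene, rose by 1.98 on the log2 scale (limma adjusted p = 0.0316), but it was well above background on 1 of 3 methanol arrays. Its 2 other probes differed by -0.12 and 0.02. The difference of hdc was -0.46 without methanol replicate 2 and 0.00, -0.41 and 0.05 without loliolide replicate 1, 2 and 3, fits in which another probe represented it. The call of hdc held in 1 of the 6 fits without an array, and that of Psy1 in 0.

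A group of named genes came close to the threshold without passing it. Wiv-1, also called LIN6, is another cell-wall invertase gene and was 1.78-fold higher with loliolide (limma adjusted p = 0.0575). The pectin methylesterase gene PME2.1 was 1.53-fold higher (limma adjusted p = 0.051). Among the genes with lower signal, GAME1, a glycosyltransferase gene of steroidal glycoalkaloid synthesis, differed by -1.39 (SE 0.28, limma adjusted p = 0.0705), and its other probe differed by -1.30. The gene yfe37 differed by -1.16 and its 2 other probes by -1.37 and -1.13. AOC, the allene oxide cyclase of jasmonate synthesis, differed by -0.83 (SE 0.18, limma adjusted p = 0.0841). SQS1, a squalene synthase gene, differed by -0.55 and its 2 other probes by -0.55 each. CHRDi differed by -1.88, Prg1 by -0.78, LOC101055606 by -0.52, PYD1A by -0.50 and MSI1 by -0.38. The adjusted p of these 5 genes lay between 0.0627 and 0.0995.

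Over all probes, 293 of 37423 tested probes changed at a limma adjusted p under 0.05. Of these, 288 were higher and 5 were lower with loliolide. At an unadjusted p under 0.05 limma counted 5503 higher and 2022 lower probes, and with array weights 2822 higher and 710 lower probes passed the adjusted threshold. At least 2-fold changes were found for 159 probes, 156 higher and 3 lower. Counting 1 probe per gene, 399 of 28295 genes changed, 389 up and 10 down, of which 9 are among the 1101 tested genes with a name. The others are unnamed accessions, each counted as 1 gene, so the number of distinct genes may be smaller. The groups did not overlap for 11037 probes, or 29.5%, where chance gives 10%. Of the changed probes, 83.6% were dimmer than the median tested probe, and 49 were not well above background on any methanol array. The unnamed probe A_96_P107449 was at least 7.57-fold higher with loliolide (limma adjusted p = 0.00825), and A_96_P199084 at least 3.69-fold higher. The unnamed probe A_96_P134197 fell by 1.38 on the log2 scale (limma adjusted p = 0.0266 counting 1 probe per gene). A_96_P126637 differed by -1.43 and passed only when 1 probe per gene was counted (limma adjusted p = 0.0431, 0.0532 over all probes). The count of changed probes was 30, 46 and 105 without methanol replicate 1, 2 and 3, and 0, 34 and 40 without loliolide replicate 1, 2 and 3 (5924 probes at an unadjusted p under 0.05 in limma without loliolide replicate 1). It was 107 after quantile normalisation, with 95 higher and 12 lower, and 65 after scaling to the spike-in controls, chosen after seeing the data.

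**Figure D2:**
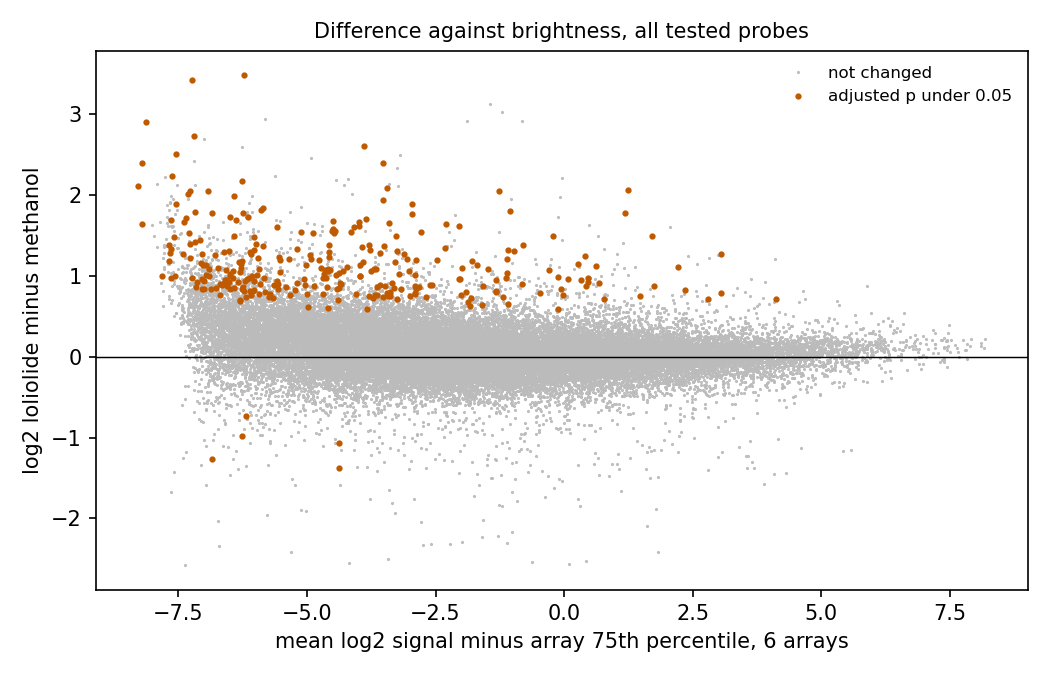
Log2 difference between loliolide and methanol (vertical axis) against the mean log2 signal minus the array's 75th percentile (horizontal axis), with 1 point per tested probe and changed probes in orange. Of 293 changed probes, 181 lie among the dimmest 25% of the probes, where the median difference was 0.25.

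Gene lists fixed before the data were examined were then tested as groups. None of the 11 lists with at least 5 tested genes shifted against the other genes (limma camera, lowest adjusted p = 0.107). Of the 18 tested ethylene genes 1 rose, ACS2, and 17 did not pass over all genes tested, while 2 rose when adjusted over the list alone. The ethylene genes were higher in 15 of 18 cases, with a median log2 difference of 0.15, or -0.15 with the spike-in scaling (limma camera adjusted p = 0.183, 0.577 with an estimated correlation). Of the 11 jasmonate genes 0 passed over all genes and 1 fell when adjusted over the list alone, and the list's median was -0.17 (limma camera adjusted p = 0.107). Of the 5 cell wall genes 0 passed over all genes and 2 rose when adjusted over the list alone, with a median of 0.40 (limma camera adjusted p = 0.485). The 6 carotenoid genes of this list had a median of -0.13, with 5 lower and 1 higher, and none passed (limma camera adjusted p = 0.107). The 13 auxin genes had a median of -0.07 and the 6 terpenoid genes a median of -0.16, with none passing in either (limma camera adjusted p = 0.107 for both). The 8 heat shock genes had a median of 0.11 and the 10 cytochrome P450 genes a median of 0.25, with none passing in either and medians of -0.19 and -0.05 with the spike-in scaling. That scaling moved the median of all probes from 0.06 to -0.24. Of the 8 pathogenesis-related genes none passed over all genes, while 1 rose and 1 fell when adjusted over the list alone. Their median was 0.04 and their mean -0.08, and the median was -0.01 with quantile normalisation and -0.26 with the spike-in scaling. The 6 WRKY genes had a median of 0.11, or -0.19 with the spike-in scaling, and the 5 receptor kinase and calcium genes a median of 0.00, or -0.30. None of these genes passed, and neither list shifted (limma camera adjusted p = 0.975 and 0.485).

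The second comparison set the authors' deposited table of loliolide-responsive probes against the arrays. The authors' deposited table lists 27 probes, of which 1 has a gene name here, lin5, with a mean log2 ratio of 1.75 in the authors' deposited table. All 27 probes were higher with loliolide, with groups that did not overlap. Of these, 22 passed a limma adjusted p of 0.05, and 26 did when adjusted over the list alone. The list was chosen on these samples and is not independent evidence of its direction. Requiring at least 2-fold higher signal in all 3 numbered pairs and a signal well above background on all 6 arrays gave 65 probes, of which 26 are in the authors' deposited table. Of the 39 others, 35 had a limma adjusted p under 0.05, but these were picked for a difference on the same arrays and are not independent evidence either. By the same rule 9 probes were lower. The number of deposited probes that passed was 5, 8 and 16 without methanol replicate 1, 2 and 3, and 0, 4 and 8 without loliolide replicate 1, 2 and 3. All 27 stayed higher in each of these fits, which their non-overlapping groups made certain.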

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

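The choice of these controls was made after the result was seen. Of 59 kinds of control spots, 28 were well above background on all 6 arrays. After scaling, the loliolide arrays lay above the methanol arrays for 27 of these 28 controls, and the groups overlapped for 1. Many of the 28 belong to the E1A or DCP sets, whose members may not be independent of each other. In unscaled median spot signal minus median background, (+)E1A_r60_a20 read 707.9 to 761.9 with methanol and 774.6 to 813.7 with loliolide. In this measure the groups of GE_BrightCorner overlapped. The difference of (+)E1A_r60_a20 was 0.28 in the scaled processed signal, which differs from this measure in more than the scaling. The comparisons as reported do not use these controls, while the alternative scaling to the median of the 10 E1A spike-ins does use those. The spike-in (+)E1A_r60_3, with 32 spots per array, differed by 1.26 on the log2 scale between loliolide (-2.71 ± 0.06, SD, n = 3) and methanol (-3.97 ± 0.05, SD, n = 3). The 9 other spike-ins of its set differed by 0.23 to 0.41. Another 5 of the 28 controls lay above that range, ETG10_236652 at 0.79, DCP_22_9 at 0.70, DCP_20_7 at 0.56, DCP_22_7 at 0.53 and DCP_22_6 at 0.44. The control whose groups overlapped, (+)eQC-40, differed by 0.00. DCP_1_11 was also higher with loliolide, but it was well above background on only 3 of the 6 arrays, so no size is given.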

How the results depend on the processing

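The normexp correction on median signals, cyclic loess, the spike-in scaling, the named-gene background and the added lists were chosen after seeing the data. The cause was not tested for any of the shifts given here. The planned normexp correction on mean signals was not run, since the scanner tables used here hold no mean signal, and the slide could not be fitted as a block. As reported, 293 probes changed, the count of probes changed at least 2-fold was 159 and the count of genes changed was 399. In this order, the values were 95, 28 and 118 with normexp on median signals, 107, 71 and 129 with quantile normalisation, and 99, 67 and 134 with cyclic loess. They were 65, 64 and 71 with the spike-in scaling, which moved the median of all probes from 0.06 to -0.24, and 154, 103 and 192 with a variance trend and robust eBayes. Array weights gave 3532, 526 and 3112. Median centring gave 189 probes, and requiring a signal well above background on all 6 arrays gave 190 probes and 97 changed at least 2-fold. With normexp 14 deposited probes passed, against 22. The offset of 50 in normexp shrinks the log2 differences of dim probes by construction, so its counts do not isolate background correction. The replicate block gave 0 changed probes (5185 at an unadjusted p under 0.05 in limma), 0 changed at least 2-fold, 0 genes and 0 deposited probes. Whether the numbers pair the samples is not stated in the labels. Same-numbered arrays deviated from their group means with correlations of -0.16, -0.14 and -0.46, and 0 of the 3 loliolide arrays correlated best with its own number. With 3 arrays per group, these correlations cannot show whether a pairing existed. Without each array in turn the counts ranged from 0 to 105 probes, 0 to 100 changed at least 2-fold, 41 to 237 genes and 0 to 16 deposited probes. The count without loliolide replicate 2 lay at the threshold, with 34 probes when the filter used 5 arrays and 0 when it used 6, where the lowest limma adjusted p was 0.0501. Without loliolide replicate 1 the count was 0 with both filters. The lowest limma adjusted p was then 0.0601 with 5 arrays and 0.0624 with 6. Of the 293 probes, 100 were also called with quantile normalisation, 94 with cyclic loess and 60 with the spike-in scaling, and all 293 kept their sign in these 3. Of the planned lists, where 0 shifted, 2 shifted with normexp, 1 with the mean over a gene's probes and 0 to 3 without each array. Of the added lists, where 2 shifted, 7 shifted with normexp, 4 with the mean over a gene's probes, 5 with the named-gene background (3 up, 2 down), 1 with quantile normalisation, 1 with cyclic loess, 1 without the filter, 0 with an estimated correlation, 0 with fry and 1 to 6 without each array. The difference of Psy1 was -0.12 with the mean over its probes. That of hdc ranged from -0.46 to 1.93 without each array in turn. For the named genes that passed, 73 of 160 comparisons kept the call, 83 lost it in the same direction and 4 reversed. Signal over background limits the dimmest probes, where most changes were called.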

Other observations

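The tests of explanations in this part were chosen only after the result was seen, and so were the splits of the counts of probes, genes and deposited probes and the named-gene background. Of 23 gene lists written from symbols after the data had been opened, 2 shifted, both downwards. Against the named genes alone 5 shifted, 3 upwards and 2 downwards. Steroidal glycoalkaloid and sterol genes had a median log2 difference of -0.35 over 12 genes, 9 lower and 3 higher (limma camera adjusted p = 0.00137, adjusted p = 0.566 with an estimated correlation, and a range over all alternatives of 1.01e-05 to 0.566). None passed over all genes tested, and 6 fell when adjusted over the list alone. Steroidal glycoalkaloids are toxic compounds of tomato leaves, and the list also holds genes of other sterol and triterpene branches. GAME1 differed by -1.39 (SE 0.28), gad2, also called GAME11, by -1.43 (SE 0.37) and GABA-TP2, also called GAME12, by -0.87 (SE 0.29). SQS1 differed by -0.55, the cycloartenol synthase gene CAS1 by -0.69 and HYD2 by -0.97. GAME3 went the other way, at 0.62, and was well above background on 1 methanol array. The 2 other members with higher signal were lTTS1 at 0.32 and CYP710A11 at 0.24. Carotenoid genes had a median of -0.09 over 21 genes (limma camera adjusted p = 0.0181, adjusted p = 0.566 with an estimated correlation), and 1 rose, Psy1, by its brightest probe alone. The adjusted p of the carotenoid list was 0.159 with quantile normalisation, 0.17 with cyclic loess, 0.119 without methanol replicate 3 and 0.0624 without loliolide replicate 1, in a range over all alternatives of 0.000906 to 0.657.

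Of 26 sugar genes 1 rose, lin5, while the acid invertase gene AI differed by 0.37 and Wiv-1 by 0.83. In this list 20 genes were higher and 6 lower, and it did not shift (limma camera adjusted p = 0.729). None of 40 cell wall genes and none of 21 gibberellin, cytokinin and brassinosteroid genes passed over all genes, and 3 of each rose when adjusted over the list alone (limma camera adjusted p = 0.187 and 0.135). Against the named genes alone both lists shifted upwards (limma camera adjusted p = 0.0395 for each, 0.674 with an estimated correlation), as did the 24 ethylene genes (limma camera adjusted p = 0.0478, 0.674 with an estimated correlation). Over all alternatives the adjusted p ranged from 0.0188 to 0.566 for the cell wall list, from 0.0379 to 0.566 for the gibberellin list and from 0.0478 to 0.79 for the ethylene list. The abscission polygalacturonase genes TAPG1 and TAPG2 differed by 1.56 and 1.79, with loliolide arrays all above methanol arrays. TAPG4 was not well above background on any methanol array and was higher by at least 1.75 on the log2 scale. The gibberellin oxidase genes 3OH-2 and GA2ox5 differed by 1.86 and 1.45, and GA2ox5 was well above background on 1 methanol array. Of 13 wound and herbivory genes 4 were higher and 9 lower, none passed over all genes, and 1 rose and 0 fell when adjusted over the list alone (limma camera adjusted p = 0.135). Their lowest values were those of LAPA1 at -2.09 (SE 0.82) and mcpi at -2.17 (SE 0.98), with groups that overlapped, while LAPA2 differed by -0.03, THT7-8 by 0.32 and sbt3 by 0.37.

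The lower signal of the glycoalkaloid list was weighed against 3 explanations. Its median was -0.346 at the highest under the other scalings, where the scaling explanation predicted 0 or higher. These scalings placed the median of all probes between -0.24 and 0.08, against 0.06 as reported. They could hardly have raised the list to 0, so this comparison does not decide on scaling. The limma camera adjusted p at the preset correlation was at most 0.0163 without each array, so the call at this setting did not rest on 1 array. This setting takes the genes of a list as nearly independent, so the comparison shows no more than that. The list's mean log2 signals, each gene centred over the 6 arrays, were 0.49, 0.13 and 0.01 on methanol arrays 1 to 3 and -0.19, -0.08 and -0.36 on loliolide arrays 1 to 3, so that methanol replicate 1 stood highest. Genes that vary together between samples of 1 group remain a candidate explanation, since the adjusted p was 0.566 with an estimated correlation. Of the 10 splits of the 6 arrays, 7 shifted at least as many of the added lists as the real 2, up to 4. The slide remains open, and a lower glycoalkaloid expression under loliolide is a hypothesis.

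Nearly all changed probes were higher with loliolide, 98.3% of 293, but with array weights the share was 79.9% of 3532, with 710 lower. An intensity-dependent difference between arrays is not the whole cause, since 89.9% of 99 changed probes were higher after cyclic loess, although it may account for part of the count. An added background on 1 slide would act on dim probes, but 100% of the 47 changed probes brighter than the median were higher. This argues against it for these 47 probes only, not for the 245 changed probes dimmer than the median. The dimmest quartile held 181 changed probes, and the median difference of all its tested probes was 0.25. In the quartiles above the median it was 0.006 and 0.033. An added background therefore remains open for the dim probes, where most changes were called. The dimmer array of loliolide replicate 3 does not explain the high share of higher probes, since 100% of 40 changed probes were higher without this array. Without loliolide replicate 1, 0 probes changed (5924 at an unadjusted p under 0.05 in limma). With 0 slides holding both groups, a slide effect and a one-way response to loliolide cannot be told apart.

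Changed probes differed more than other probes of the same transcript. For 20 higher probes with a partner of like brightness, the median was 0.82 and that of the partners 0.27, with 14 partners higher. Partners of unchanged probes of the same brightness had a median of 0.03 (permutation p = 0.00027), which argues against differences of single probes between slides as the whole cause. Partners of 19 changed probes lay below those of unchanged probes of like fold, at 0.31 against 0.45 (permutation p = 0.00348). This comparison decides nothing, since changed probes were picked for a small spread, with a median SD within groups of 0.108 against 0.285, and selection of extreme probes remains open. Whether probes reading other transcripts add to the gap was not tested, and slide and treatment remain confounded here too.

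The 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 293 changed probes, 159 changed at least 2-fold, 399 genes and 22 deposited probes, and the highest of the other splits gave 0 of each, so that 1 of 10 splits reached these values. For the deposited probes this says nothing, since they had been selected for a difference in the real split. In every split the probes tested were those that passed the filter on the real groups. The other splits mix both groups, so any difference between slides or treatments widens their spread. The real split is also the split by slide, so these counts do not tell loliolide from the slide. At an unadjusted p under 0.05 limma counted 7525 probes for the real split and up to 5517 for the others. The real split shifted 0 planned lists, which all 10 splits reach, and the highest other split shifted 2.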
